A study of Mus musculus with 6 samples.

How the data were processed

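Total RNA was extracted from kidney with TRIzol, and small RNA libraries were made with an adapter-ligation kit, PCR and size selection on gels before sequencing on a DNA nanoball instrument, per the labels' protocols. Whether molecular identifiers were used is not given in the sources used here, so PCR copies may be counted as separate molecules; ligation favours some miRNA ends over others, and size selection sets which lengths are seen. Levels of different miRNAs are therefore less comparable than levels of the same miRNA between libraries. The submitters' processing notes name Bowtie2, DESeq2 and the genome build GRCm38.p6, with no version or role for the tools; the miRNA annotation, the treatment of reads that match several miRNAs and the treatment of strand are not given in the sources used here. The deposited values are whole-number counts per mature miRNA in 1 table made by the authors, with no normalization, and include entries that the authors predicted and that carry no miRBase name. How reads that match several entries were assigned is not known, so entries with similar sequences are uncertain: C57BL/6 replicate 3 had 242 counts for miR-199a-3p and 15070 for miR-199b-3p, while the other libraries had at least 12448 and at most 228.

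The 6 columns were matched to samples by group, age and replicate number in the column names and titles; the column names are not the titles themselves. All 6 libraries were used, as 3 C57BL/6 and 3 MRL/lpr samples. Totals ran from 5259528 to 6773829 counts, so a miRNA with a few counts has a wide counting error, which for such libraries covers counting only. Within groups, counts of library pairs differed far beyond sampling noise (chi-square per degree of freedom from 151 to 895), so no library was a copy of another.

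Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. miRNAs were kept by filterByExpr with group sizes (minimum count 10, minimum total 15), scaled by TMM, fitted with a quasi-likelihood model with robust dispersion (biological coefficient of variation 35.1%) and tested for group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled. Fold changes are fitted, and standard errors were derived from the coefficient and its F statistic. Lists of leukocyte, myeloid, NF-κB-induced, lupus lymphoid, Dlk1-Dio3, Sfmbt2, mesenchymal, injury, miR-29, miR-200, kidney epithelium, miR-30, endothelial, erythroid, miR-17-92, miR-322 and miR-503 cluster, let-7, muscle, liver, neuroendocrine and reference miRNAs were fixed before the data were examined and matched by mature name. The 20 lists with at least 2 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, two-sided. Arm usage was tested with limma on log2 of the ratio of 5p to 3p CPM, after adding 1. Library summaries were compared by exact two-sided permutation. The named miRNAs were those past the threshold with groups that do not overlap and a mean of at least 100 CPM (up to 10 in each direction), the 5 most abundant, and for each list up to 4 members past the threshold or else the 2 most abundant; predicted entries were counted but not named. Hairpin positions come from GENCODE M21 (GRCm38, the build the notes name), matched by hairpin name.

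The tests were tried on simulated counts with the means, dispersions and library sizes of the 451 tested miRNAs, 200 of them changed. edgeR called 40% of the 2-fold and 96% of the 4-fold changes, none with the wrong sign, and 3 unchanged miRNAs, and called 0 in a simulation without change. With 200 of 451 miRNAs changed and all drawn independently, these shares may overstate what the test finds in the real libraries. With 15 simulated lists, camera called 2 of 2 moved lists and 0 others, on independently drawn miRNAs. The arm test called 13 of 20 hairpins with a 4-fold shift and 1 other out of 105. Alternatives were RLE, upper-quartile and library-size scaling, TMM without the 10 most abundant miRNAs, no filter or a filter of 10 CPM in 3 libraries, DESeq2 1.42.0 with its own independent filtering in place of filterByExpr, limma-voom, edgeR without robust dispersion, a fold minimum, the replicate number as a block, other pseudocounts and each library left out. After seeing the data, 3 alternatives were added for the test of single miRNAs: summing entries with the same miRNA number and arm, leaving out predicted entries, and DESeq2 on the miRNAs kept by filterByExpr. The kidney injury list was then also followed through the alternatives. Figures were drawn with matplotlib 3.10.9.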

Results

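MicroRNAs were sequenced from kidneys of 17-week-old female mice of 2 strains, with 3 libraries for each strain. MRL/lpr mice carry the lpr mutation of the Fas gene on the MRL background and develop a spontaneous lupus-like disease that includes nephritis, and C57BL/6 mice were the controls. The comparison asks which kidney microRNAs (miRNAs, short RNAs that repress messenger RNAs) differ between the strains. The C57BL/6 libraries held 5430246, 6213520 and 6773829 counts for replicates 1, 2 and 3, and the MRL/lpr libraries held 6460200, 5259528 and 5551271. The table lists 1542 mature sequences, of which 1190 carry a miRBase name and 352 are the authors' predicted entries, and 451 passed the filter on low counts and were tested. The most abundant sequences were let-7f-5p, miR-126a-3p, miR-26a-5p, let-7g-5p and let-7c-5p. None of these 5 passed the test, with log2 fold changes (MRL/lpr over C57BL/6) from -0.33 for let-7c-5p to 0.0013 for let-7g-5p. The 10 most abundant miRNAs took 52.1% ± 1.84 of the counts in C57BL/6 and 50.7% ± 1.97 in MRL/lpr (SD, n = 3; exact two-sided permutation p = 0.4, where 0.1 is the smallest p that 3 against 3 can give). Detected sequences numbered 915 ± 38.5 in C57BL/6 and 905.7 ± 29.1 in MRL/lpr (SD, n = 3; exact permutation p = 0.8), and total counts gave an exact permutation p of 0.6.

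In the kidneys of MRL/lpr mice 19 miRNAs were higher and 9 were lower than in C57BL/6 kidneys (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these 28, 24 carried miRBase names (19 higher, 5 lower) and the other 4, all lower, were predicted entries. The higher miRNAs included miR-204-5p, an abundant epithelial miRNA, both arms of miR-802, a kidney- and liver-enriched miRNA, miR-92b-3p, and miR-155-5p, which is induced in activated lymphocytes and macrophages. The lower ones included miR-383-5p, which was nearly absent from MRL/lpr kidneys and had the smallest p of all miRNAs tested. At least 2-fold differences were seen for 25 of the 28 calls (18 higher, 7 lower). With library size alone in place of TMM scaling, which moved the median of all tested miRNAs by 0.15 on the log2 scale, the split was 24 higher and 6 lower, so each change is relative to the scaling.

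miR-204-5p rose 2.88-fold, from 5195 ± 815 to 14945 ± 2090.2 CPM (counts scaled to a common library total; SD, n = 3; log2 fold change 1.52 ± 0.18 SE, edgeR adjusted p = 0.00141). Its hairpin lies on chromosome 19 (GRCm38, 22750605 to 22750672, plus strand) in an intron of Trpm3. The minor arm of the same hairpin, miR-204-3p, was also higher (log2 fold change 2.46 ± 0.50, edgeR adjusted p = 0.0186), at 0.983 ± 0.600 CPM in C57BL/6 and 5.63 ± 1.49 CPM in MRL/lpr. miR-802-5p rose 3.35-fold, from 55.2 ± 20.01 to 185 ± 14.5 CPM (log2 fold change 1.75 ± 0.29, edgeR adjusted p = 0.00793). Its hairpin lies on chromosome 16 (93369720 to 93369816, plus strand) and overlaps no host gene in the GENCODE M21 annotation. miR-92b-3p rose 2.44-fold, from 191 ± 16.4 to 466 ± 47.6 CPM (edgeR adjusted p = 0.00577), and its hairpin lies on chromosome 3 (89227116 to 89227198, minus strand). miR-155-5p rose 2.47-fold, from 70.1 ± 28.1 to 173 ± 27.5 CPM (edgeR adjusted p = 0.0331), and its hairpin lies in an exon of its host transcript Mir155hg on chromosome 16 (84714140 to 84714204). miR-467a-5p rose 2.06-fold (edgeR adjusted p = 0.0154), and miR-125b-5p rose 1.84-fold, from 467 ± 124 to 859 ± 37.4 CPM (edgeR adjusted p = 0.0451). Both are made from more than 1 locus, so their source hairpin is not known.

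miR-383-5p was 54.2-fold lower in MRL/lpr, at 76.1 ± 25.5 CPM in C57BL/6 and 1.34 ± 0.927 CPM in MRL/lpr (SD, n = 3; log2 fold change -5.76 ± 0.49 SE, edgeR adjusted p = 1.89e-04). Its counts were 249, 634 and 485 in the C57BL/6 libraries and 17, 5 and 4 in the MRL/lpr libraries, and without MRL/lpr replicate 1 its log2 fold change was -6.50. Its hairpin lies on chromosome 8 (38252133 to 38252202, minus strand) in an intron of Sgcz. It was singled out after its values were seen, since its mean was below the minimum for named miRNAs. miR-375-3p, a miRNA of neuroendocrine and secretory epithelial cells, fell 2.29-fold, from 727 ± 83.0 to 318 ± 37.5 CPM (edgeR adjusted p = 0.00793), and its hairpin lies on chromosome 1 (74900658 to 74900721, minus strand). miR-31-5p fell 1.89-fold (82.2 ± 12.7 to 43.5 ± 5.78 CPM, edgeR adjusted p = 0.0451). Also named after their values were seen, miR-181a-2-3p and miR-676-3p were lower by 2.14-fold and 1.96-fold.

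**Figure D1:**
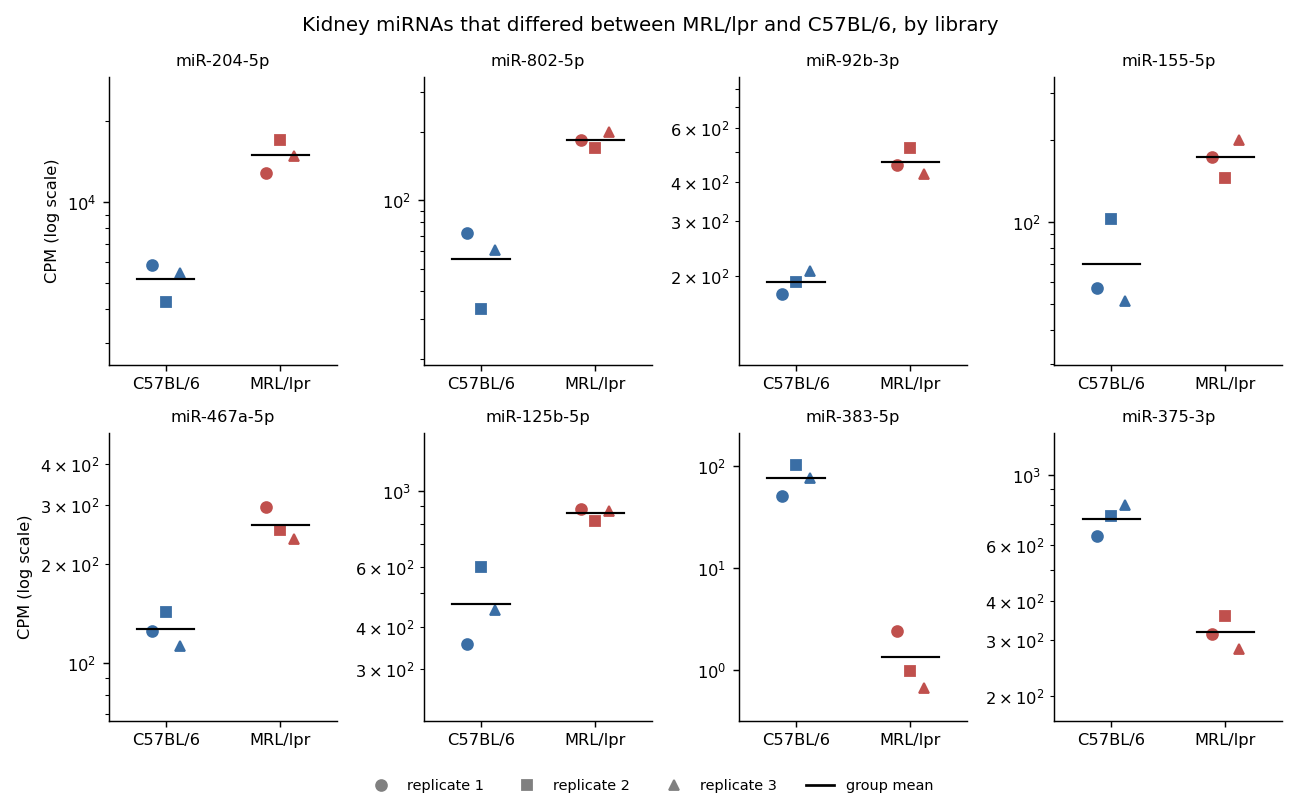
CPM (log scale) of 8 miRNAs past the threshold in each library, with C57BL/6 in blue and MRL/lpr in red, the replicate number given by the marker and the group mean by a black line. In each panel the 3 MRL/lpr libraries lie on one side of the 3 C57BL/6 libraries, and miR-383-5p averages 76.1 CPM in C57BL/6 and 1.34 CPM in MRL/lpr.

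The remaining higher miRNAs included 3 members of the families described next and 10 others, named after their values were seen. Besides miR-204-3p, the 10 were miR-3073b-3p and miR-3073b-5p, miR-129-2-3p, miR-3473b, miR-802-3p, miR-708-5p, miR-193a-3p, miR-489-3p and miR-211-5p. Their log2 fold changes ran from 1.13 for miR-708-5p to 2.95 for miR-3073b-3p. Values for at least 3 of them are uncertain, and reads of the others, such as miR-3473b, were not checked for matches elsewhere in the genome. The miR-3073b hairpin (chromosome 12, 112109250 to 112109309, minus strand) lies antisense to Mir3073a, and how the authors counted strands is not given in the sources used here. The hairpins of miR-211 and miR-204 share a stretch of 17 bases, and how reads that match both were counted is not given in the sources used here.

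The values of the groups did not overlap for any of the 28 calls, and they did not overlap for 130 of the 451 miRNAs (28.8%, against 10% by chance for 3 against 3). The number of calls changed with the library left out. It was 15, 54 and 11 without C57BL/6 replicates 1, 2 and 3. Without MRL/lpr replicates 1, 2 and 3 it was 19, 30 and 5. A test with fewer libraries has less power, so a lower number alone does not show that calls rest on a single library. All 28 calls kept their direction in each of these runs. miR-204-5p, miR-92b-3p and miR-383-5p passed under every alternative that kept entries separate, and each of the other 21 named calls missed the threshold under at least 1. The misses ran from 1 of 18 alternatives, as for miR-802-5p, to 10 of 18 for miR-31-5p and 13 of 17 for miR-467b-5p. The strains differ in genetic background, the lpr mutation and disease together, and the labels do not say that each library is a separate animal, so p-values measure the spread between these samples.

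Of 21 lists of miRNAs fixed before the data were examined, 2 passed camera with a preset correlation and neither passed with an estimated correlation. The miR-466, miR-467, miR-669 and miR-297 families, whose hairpins mostly lie in introns of the imprinted gene Sfmbt2 on chromosome 2, lay higher in MRL/lpr. Of 22 members tested, 4 were higher and none was lower over all miRNAs tested, and 9 were higher when adjusted over the list alone. All 22 log2 fold changes were above 0 with TMM, RLE and library-size scaling, with a median of 0.99. The 4 were miR-467a-5p (127 ± 15.3 to 262 ± 30.6 CPM), miR-297a-5p (12.5 ± 4.19 to 30.4 ± 6.37 CPM), miR-297c-5p (10.2 ± 2.37 to 26.0 ± 8.47 CPM) and miR-467b-5p (1.22 ± 0.188 to 3.54 ± 0.665 CPM; SD, n = 3). With TMM, the lowest of the 22 log2 fold changes was 0.012 ± 1.53 SE, for miR-466b-3p. Its counts were 17, 40 and 27 in C57BL/6 and 97, 1 and 0 in MRL/lpr. Signs turned in other settings: with the replicate number as a block, 1 of the 22 log2 fold changes fell below 0. Without C57BL/6 replicate 3, 25 members were above 0 and 3 below. The list passed camera with a preset correlation (limma camera adjusted p = 9.60e-09) but not with an estimated correlation (p = 0.0846, adjusted p = 0.948). Its direction on balance did not pass fry (adjusted p = 0.199), while change in either direction did (adjusted p = 0.0394). In C57BL/6 replicate 2, 19 of the 22 were higher than in both other C57BL/6 libraries. Without it 12 of 27 members tested were higher in MRL/lpr (20 when adjusted over the list alone). The median was then 1.43, with a fry adjusted p of 0.0165 for the direction on balance. Leaving it out raises this list in MRL/lpr by construction, so these values are not separate support. The 27 are also a different set, and 1 of them was below 0. Among those added, miR-466a-3p had 0 counts in each C57BL/6 library and 24, 0 and 28 in MRL/lpr. The copies in these families are nearly identical, so counts of single members are uncertain.

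The miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, which are expressed from the maternal chromosome, lay lower in MRL/lpr. Of 48 listed names 42 were in the table and 14 were tested. None passed over all miRNAs tested, and 9 were lower when adjusted over the list alone. All 14 log2 fold changes were below 0 with TMM, RLE and library-size scaling, with a median of -0.98. Without MRL/lpr replicate 2, and likewise without MRL/lpr replicate 3, 1 of 17 members tested was above 0. miR-127-3p had 260.3 ± 51.8 CPM in C57BL/6 and 132 ± 35.4 CPM in MRL/lpr (SD, n = 3; log2 fold change -0.98 ± 0.26 SE, edgeR adjusted p = 0.0503). miR-411-5p had 163 ± 53.6 and 83.5 ± 23.8 CPM (edgeR adjusted p = 0.0836). The list passed camera with a preset correlation (adjusted p = 2.21e-06) but not with an estimated correlation (p = 0.0948, adjusted p = 0.948). fry gave adjusted p = 0.199 for the direction on balance and 0.0383 for change in either direction. In C57BL/6 replicate 2, 12 of the 14 were higher than in both other C57BL/6 libraries, and without it 4 of the 14 were lower in MRL/lpr when adjusted over the list alone, with a median of -0.79 and a fry adjusted p of 0.0468 for the direction on balance.

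**Figure D2:**
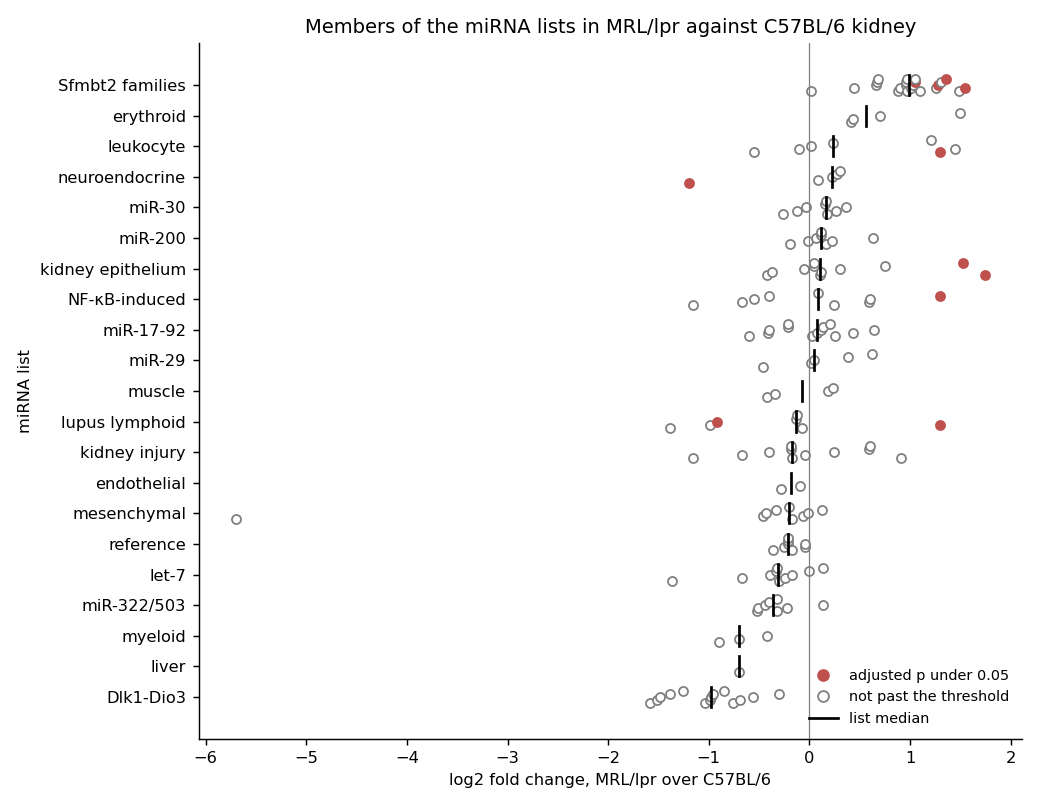
Log2 fold change (MRL/lpr over C57BL/6) of each tested member of the 21 lists, 1 list per line, with filled points for members past the threshold, open points for the others and a black bar for the list median. The Sfmbt2 families have a median of 0.99 and the Dlk1-Dio3 list a median of -0.98, and the mesenchymal point at -5.70 is miR-199b-3p, whose counts trade places with those of miR-199a-3p.

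Of the other lists, 5 held 1 or 2 changed members. Among 11 kidney epithelium miRNAs, miR-204-5p and miR-802-5p rose and none fell (3 higher and 2 lower when adjusted over the list alone, and 2 higher and 1 lower without C57BL/6 replicate 2; camera adjusted p = 0.299). The abundant tubular miRNAs miR-192-5p (28243 ± 9843 and 30421 ± 2972 CPM in C57BL/6 and MRL/lpr; SD, n = 3) and miR-194-5p did not pass. Among 7 leukocyte miRNAs, miR-155-5p rose (2 higher when adjusted over the list alone; camera adjusted p = 0.223), and it was also the 1 member past the threshold among 9 NF-κB-induced miRNAs (1 higher when adjusted over the list alone; camera adjusted p = 0.804). In C57BL/6 replicate 2, all 7 and all 9 members of these lists were higher than in both other C57BL/6 libraries. Among 7 miRNAs that earlier work found raised in lymphoid cells of lupus mice, miR-155-5p rose and miR-31-5p fell (1 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.444). Its members miR-127-3p and miR-379-5p are also in the Dlk1-Dio3 list. The median of the lupus lymphoid list was -0.14, 0.0096 with library-size scaling and -0.015 without C57BL/6 replicate 2. In that library all 7 members were higher than in both other C57BL/6 libraries. miR-375-3p was the 1 change among 5 neuroendocrine miRNAs (1 lower when adjusted over the list alone), whose median log2 fold change was 0.22, with a mean of -0.061 and a camera direction of down (adjusted p = 0.931). For change in either direction, fry gave adjusted p = 0.0119 for the kidney epithelium and lupus lymphoid lists and 0.0239 for the neuroendocrine list.

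No member passed in the other 14 lists. Among 11 kidney injury miRNAs the median log2 fold change was -0.17 and the mean -0.041, while the direction of camera was up (adjusted p = 0.931); miR-21a-5p had 15382 ± 9629.7 CPM in C57BL/6 and 18284 ± 2419.8 in MRL/lpr (SD, n = 3). In C57BL/6 replicate 2, 9 of the 11 were higher than in both other C57BL/6 libraries, and without it the median of the list was 0.40 (8 members above 0 and 3 below; camera adjusted p = 0.169). The myeloid list had a median of -0.70 over 3 members (camera adjusted p = 0.804), with miR-223-3p at 492 ± 457 and 367 ± 35.4 CPM and miR-511-3p at 63.1 ± 77.7 and 34.0 ± 4.72 CPM in C57BL/6 and MRL/lpr (SD, n = 3). Without C57BL/6 replicate 2, all 3 myeloid log2 fold changes were above 0, with a median of 0.71 (camera adjusted p = 0.120, fry adjusted p = 0.0165). The erythroid median was 0.57 (0.25 without C57BL/6 replicate 2 and 1.30 without C57BL/6 replicate 3). Its members miR-486a-5p and miR-486b-5p had few counts that varied widely between libraries. Medians were 0.16 for miR-30 (-0.022 without MRL/lpr replicate 3), 0.11 for miR-200, 0.046 for miR-29 and 0.076 for miR-17-92 miRNAs (-0.070, -0.040 and -0.040 without C57BL/6 replicate 1, C57BL/6 replicate 3 and MRL/lpr replicate 3). They were -0.078 for muscle (0.062 with library-size scaling and 0.19 without MRL/lpr replicate 1), -0.19 for endothelial, -0.20 for mesenchymal (0.085 without C57BL/6 replicate 2), -0.21 for qPCR reference, -0.31 for let-7 and -0.36 for the miRNAs of the X-linked miR-322 and miR-503 cluster. Camera adjusted p for these 11 lists ran from 0.223 to 0.957. Their more abundant members did not pass: miR-451a had 2303 ± 1517 CPM in C57BL/6 and 3741 ± 470.2 in MRL/lpr, miR-143-3p had 32041 ± 3670 and 25458 ± 3790, and miR-429-3p had 31152 ± 9032 and 33706 ± 3497 (SD, n = 3). One miR-29 member, miR-29b-3p, was higher when adjusted over the list alone (log2 fold change 0.62, edgeR adjusted p = 0.0731 over all miRNAs), and no longer so without C57BL/6 replicate 2. The liver miRNA miR-122-5p was the 1 tested member of its list, at 7.65 ± 3.38 CPM in C57BL/6 and 4.77 ± 3.44 CPM in MRL/lpr (SD, n = 3).

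C57BL/6 replicate 2 stood apart from the other C57BL/6 libraries in leukocyte, myeloid and injury miRNAs. miR-146a-5p had 25574 CPM there against 5011 and 4765 CPM in replicates 1 and 3, the granulocyte miRNA miR-223-3p had 1019 against 221 and 235 CPM, and the macrophage miRNA miR-511-3p had 153 against 21.3 and 15.3 CPM. All 7 leukocyte and all 3 myeloid members tested were higher there than in both other C57BL/6 libraries. The erythrocyte miRNA miR-451a was lower, with 593 against 2829 and 3488 CPM. Kidney epithelium miRNAs had a median ratio of 0.757 to the mean of the other C57BL/6 libraries, and 1 of 11 was higher than in both; miR-192-5p had 17466 against 36759 and 30503 CPM, and miR-802-5p had 33.1 against 72.02 and 60.6 CPM. Without this library, 42 miRNAs were higher and 12 lower in MRL/lpr, and 27 of the 28 calls were kept. The library was singled out for high leukocyte, myeloid and injury values and was also high in all 9 NF-κB-induced members. Leaving it out raises these lists in MRL/lpr by construction, so their results without it are not separate support for a strain difference. The same holds for the Sfmbt2 families, of which 19 of 22 were higher there than in both other C57BL/6 libraries. Without this library, 4 of the leukocyte miRNAs were higher in MRL/lpr. Their log2 fold changes were 2.21 for miR-142a-3p, 1.95 for miR-142a-5p, 1.71 for miR-155-5p and 0.74 for miR-146a-5p. The leukocyte list then passed camera (adjusted p = 0.00128, against 0.193 to 0.536 in the other settings run; p = 0.169 and adjusted p = 0.676 with an estimated correlation), and so did the NF-κB-induced list (adjusted p = 0.0174, against 0.566 to 0.991; p = 0.154 and adjusted p = 0.676 with an estimated correlation). For the direction on balance, fry passed no list with all 6 libraries, and the Sfmbt2 and Dlk1-Dio3 lists were the 2 under 0.05 before adjustment. Without this library it passed 8: besides the Sfmbt2, Dlk1-Dio3 and myeloid lists, these were the kidney epithelium (adjusted p = 0.0165), lupus lymphoid (0.0332), leukocyte (0.0468), NF-κB-induced (0.0468) and endothelial (0.0492) lists. Of these 8, camera with a preset correlation did not pass the myeloid (adjusted p = 0.120), kidney epithelium (0.717; 6 members above 0 and 5 below), lupus lymphoid (0.653) and endothelial (0.717) lists. With an estimated correlation it passed none, with the smallest adjusted p at 0.326 for the Sfmbt2 families. miR-511-3p in the myeloid list rose by 0.93, and miR-21a-5p and miR-21a-3p in the injury list by 0.92 and 2.03, on the log2 scale. The lists overlap, so their passes are not separate results. Of the NF-κB-induced members then higher, miR-146a-5p and miR-155-5p are also leukocyte members, and miR-21a-5p and miR-21a-3p are also injury members.

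**Figure D3:**
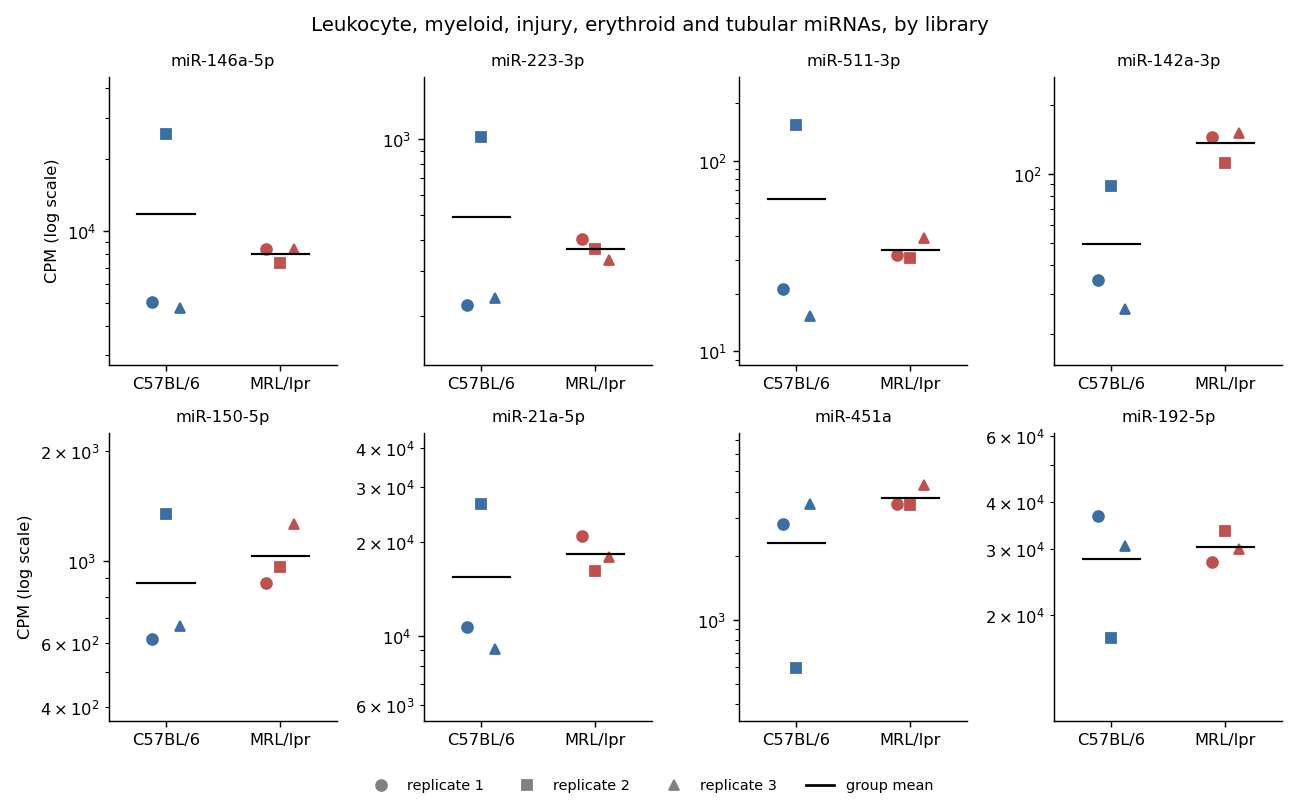
CPM (log scale) of 8 miRNAs in each library, with C57BL/6 in blue and MRL/lpr in red, the replicate number given by the marker and the group mean by a black line. C57BL/6 replicate 2 (blue square) lies above the other C57BL/6 libraries for miR-146a-5p (25574 CPM) and the next 5 miRNAs, and below them for miR-451a (593 CPM) and miR-192-5p (17466 CPM).

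The balance between both arms of a hairpin depends little on library scaling. Of 105 hairpins with both arms tested, none passed in limma on the log2 ratio of the 5p to the 3p arm, and 14 had an unadjusted p under 0.05. The smallest adjusted p, 0.0909, belonged to miR-193a, miR-674 and miR-203b. The log2 ratio for miR-193a was 2.48 ± 0.31 in C57BL/6 and 0.88 ± 0.50 in MRL/lpr (SD, n = 3), and those for miR-674 were 0.066 ± 0.26 and 1.06 ± 0.13. miR-193a and miR-674 passed when both arms had to reach 10 CPM in 3 libraries. Without MRL/lpr replicate 2, 2 hairpins passed, and with 10 CPM added to both arms 4 did, each count including miR-193a. Of the 4, miR-204 (1.02) and miR-467a (0.70) had a difference in log2 ratio of the opposite sign to that with 1 CPM added (-0.24 and -0.12), so these calls rest on the added 10 CPM.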

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

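Against 28 calls (19 higher, 9 lower), RLE, upper-quartile, library-size scaling, TMM without the 10 most abundant miRNAs, 10 CPM in 3 libraries, limma-voom and a 2-fold minimum gave 21 to 34. The count moved over 1.5 times with no filter (64 calls: 34 higher, 30 lower). It did so too with DESeq2, which was run on the unfiltered table with its own filtering (51 calls: 32 higher, 19 lower, 27 shared). edgeR without robust dispersion called 5 lower, against 9. DESeq2 still gave 48 calls on the 451 miRNAs kept by the count filter, so the unfiltered table alone does not account for its count. The causes were otherwise not tested. Leaving out each library gave 5 (without MRL/lpr replicate 3) to 54 calls (without C57BL/6 replicate 2), with 2 to 42 higher and 3 to 15 lower; 11 were called without C57BL/6 replicate 3 and 15 without C57BL/6 replicate 1. The 24 named calls kept their direction in all 428 values under alternatives and the threshold in 323. Chosen after seeing the data, DESeq2 on the 451 miRNAs kept by the count filter gave 48 calls (32 higher, 16 lower; 27 shared), summing entries of the same number and arm gave 23 calls and leaving out predicted entries 25. The replicate number as a block gave 13 calls (8 higher, 5 lower), but the numbers do not pair the libraries: the correlations of deviations were -0.34, 0.020 and -0.33 for numbers 1, 2 and 3. Lists past the threshold numbered 2, and 2 to 4 with a library left out (4 without C57BL/6 replicate 2), and 0 with an estimated correlation, where the Dlk1-Dio3 (median -0.98) and Sfmbt2 (0.99) lists no longer passed. Their medians ran from -1.15 to -0.79 and from 0.85 to 1.43 with a library left out. Below the threshold, leave-one-out medians ran from -0.072 to 0.74 for the leukocyte, -1.14 to 0.71 for the myeloid and -0.057 to 0.74 for the NF-κB-induced list. They ran from -0.32 to 0.40 for the kidney injury list, followed after seeing the data. Each was highest without C57BL/6 replicate 2, where the leukocyte and NF-κB-induced lists passed (adjusted p = 0.676 for both with an estimated correlation in camera). Most members of these lists were high in that library, so leaving it out raises the lists by construction. Arm usage had 0 calls, 4 with 10 CPM added (miR-204 and miR-467a with the sign turned, from -0.24 to 1.02 and -0.12 to 0.70), 2 with both arms at 10 CPM in 3 libraries, fewer hairpins being tested, and 0 to 2 with a library left out (2 without MRL/lpr replicate 2). The difference in detected sequences was -9.33, and 9.33 and 6.33 at minimums of 5 and 10 counts. Pseudocounts and filters planned for normalized units did not apply to counts. Low counts limit what can be said of miRNAs under the filter.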

Other observations

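The miRNAs named in this paragraph and the tests on miR-383-5p, C57BL/6 replicate 2 and miR-199 were chosen after the results were seen, and the tests on other splits of the libraries before. Without C57BL/6 replicate 2, 27 miRNAs passed that did not pass with all 6 libraries, 24 of them higher in MRL/lpr. miR-148a-3p, known to act in B cell tolerance, was higher (log2 fold change 2.08 ± 0.31 SE, edgeR adjusted p = 0.00520, against 1.26 and 0.243 with all libraries). It had 196 CPM in C57BL/6 replicate 2, 65.3 and 57.02 CPM in replicates 1 and 3, and 196 to 359 CPM in MRL/lpr. miR-135a-5p (2.64), miR-125b-1-3p (2.74) and miR-184-3p (4.24) were also higher. miR-483-3p, from an intron of Igf2, was lower (-3.83). Several of these have few counts, and of the 54 calls made without this library, the library lies nearer the other C57BL/6 libraries for 29 and nearer the MRL/lpr libraries for 25.

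miR-383-5p was nearly absent from MRL/lpr kidneys. Library scaling is argued against, since the log2 fold change nearest 0 over 4 scalings was -5.62. These scalings moved the median of all tested miRNAs by at most 0.15 on the log2 scale, so no other outcome was likely. A strain variant in the counted sequence may keep its reads from being assigned; the other arm of the hairpin would then be at similar levels, but miR-383-3p had 6 reads in all 6 libraries, too few to decide. Lower expression from the MRL background, the lpr mutation or disease also stays open and was not tested, as the design joins them.

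C57BL/6 replicate 2 held more leukocyte, myeloid and injury miRNAs than the other C57BL/6 libraries, and less of the kidney epithelium miRNAs (median ratio 0.757). Whole blood left in the tissue is argued against, since the 4 tested erythroid miRNAs had a median ratio of 0.151 to the mean of the other C57BL/6 libraries. The ratio was 0.188 for the abundant miR-451a and 0.0758 for miR-144-3p. It was 0.114 for miR-486a-5p and 0.660 for miR-486b-5p. These last entries are uncertain, with 26, 3 and 20 counts and 2, 13 and 38 counts in C57BL/6 replicates 1, 2 and 3. An MRL/lpr kidney under this label is argued against, since its miR-383-5p was 42.4 times that of the highest MRL/lpr library. More leukocyte and myeloid RNA in that kidney stays open: 10 of 10 tested list members were higher than in both other C57BL/6 libraries, with miR-223-3p at 1019 CPM and miR-146a-5p at 25574 CPM, but these miRNAs are what set the library apart, so the count decides nothing. At least 7 in 10 members were also higher there in 5 other lists without those 10, among them Dlk1-Dio3 (12 of 14), Sfmbt2 (19 of 22) and NF-κB-induced (7 of 7).

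miR-199a-3p and miR-199b-3p traded places between libraries: C57BL/6 replicate 3 had 242 and 15070 counts, and the other libraries had 12448 to 36207 and 6 to 228. Reads of a shared sequence given to a single name in each library are a candidate explanation. On the 3p side, the miR-199b hairpin shares a stretch of 28 bases with 1 miR-199a hairpin and 27 with the other. Reads from within this stretch cannot be told apart by sequence. The summed CPM had a coefficient of variation of 41.6%, against 66.0% and 231% for each name alone. A switch between the hairpins in that kidney is argued against, since miR-199b-5p took 4.60% of both 5p arms there (95% Wilson interval 3.98% to 5.31%), and 3.58% to 6.43% in the other libraries. How the authors assigned such reads is not given in the sources used here. Both names were kept as separate members of the mesenchymal list and as separate hairpins in the arm test, so their values there are uncertain.

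The 6 libraries can be split into 10 pairs of groups, too few for a share under 0.05. The real split gave 28 miRNAs past the threshold and the highest other split gave 0, so 1 of the 10 splits gave as many. For lists, the real split gave 2 and the highest other 6, and 7 of the 10 splits gave as many. Both splits with 6 lists set C57BL/6 replicates 1 and 3 against C57BL/6 replicate 2. Whether that library alone or members of a list varying together gave these counts was not tested. For the Sfmbt2 families another split gave a smaller camera p (6.27e-13) than the real split (4.80e-10), and for Dlk1-Dio3 another gave 4.69e-07 against 2.21e-07, while the real medians (0.99 and -0.98) were farther from 0 than those of the others, which reached 0.75 and 0.71. For hairpins both the real and the highest other split gave 0, so all 10 gave as many.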
